A study of Homo sapiens with 4 samples.

How the data were processed

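RNA from HCT116 cells, an established human colorectal carcinoma line, was profiled on Illumina HumanHT-12 v4 bead arrays 72 h after transfection with 40 nM siRNA. The 4 arrays form 2 groups of 2. The control siRNA group holds replicates 1 and 2, and the Las1L siRNA group holds 1 array of siRNA #1 and 1 array of siRNA #2, treated as 2 replicates of LAS1L depletion. No label says that the control arrays come from separate cultures, so the spread between them may be technical. The 2 Las1L arrays carry different siRNAs, so the spread between them also holds differences between the siRNAs. The p-values of single genes measure only the spread between these samples, in part shared across genes. Those of gene lists in camera, described below, also rest on the spread across genes.

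The deposited value table holds probe intensity on a linear scale, and GenomeStudio is the software the submitters' processing notes name, with the version not given in the sources used here. The background and normalization options are not given in the sources used here either. The deposited intensity values reach 37641 and lie below 0 for 26.9% of probes on each array, as background-subtracted values do. Their median is 14.9 on each of the 4 arrays, and the sorted values are nearly the same across arrays, as after quantile normalization. The scale was read from the values as linear with no centring per gene. A second table of signals and detection p-values was not used, because its 8 columns of values carry names that match no sample's labels. The planned background correction from detection p-values therefore could not be run, and the deposited normalized values, planned as an alternative source, were used in its place.

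Values under 16 were set to 16 and log2 was taken, so fold changes of genes that reach this floor are bounded. The floor lies under the background limit given below, so noise can also enlarge the fold changes of dim genes. The noise of the background was estimated as the root mean square of the values below 0, 17.1 signal units, and the background limit was the one-sided 0.05 point of that noise, 28.1 signal units. Probes above this limit on at least 2 of the 4 arrays were tested. This signal filter stands in for the planned filter on detection p-values and was chosen after the data were examined. It left 17689 of 47323 probes. On each array 36.5% of probes were above the limit. The number of arrays limits the precision.

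Probe names came from a platform annotation of 2016, updated to the symbols of the RefSeq annotation of GRCh38.p14, which was used for names only. Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 had none, and 30092 symbols were matched in the update. A gene was represented by its tested probe with the highest mean log2 value, which gave 10466 genes. Among the 2579 genes with more than 1 tested probe, 247 had at least 2 probes past the threshold in the intensity-trend fit, and in 7 of these the probes had opposite signs (ZMAT3, CTSC, SNU13, RFC3, MSI2, BCCIP and EID2B).

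The primary test, fixed before the data were examined, was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) with 2 groups, no intensity trend, two-sided p-values and Benjamini-Hochberg adjustment over all tested probes at 0.05. The same fit with an intensity trend, in which the prior variance depends on mean signal, was planned as an alternative. The prior variance, shared across genes, weighed as 13.8 degrees of freedom with the trend and 2.21 without it. Each gene's own residuals gave 2, so standard errors and p-values of the trend fit rest mostly on the shared variance. After the primary fit had passed no gene, the trend fit was also carried through as a result of its own, and each statement resting on it names it or follows the convention given with the counts. Each siRNA was compared with the control pair, and with the other siRNA, in a fit of 3 groups with 1 residual degree of freedom, where a lone array is assumed to vary like the controls.

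Both tests were tested on simulated data for the comparison of Las1L siRNA with control siRNA, with 11283 genes tested. A single draw held 164 changed genes among them. The fit without a trend recovered 0% of genes changed by 1.5-fold, by 2-fold or by 4-fold. The trend fit recovered 9.09% of those changed by 1.5-fold, 58.5% of those changed by 2-fold and 78.6% of those changed by 4-fold, with 0 false calls. With no changed gene, each fit called 0 of 11362 genes. The share of changed genes affects recovery after adjustment, and the simulated noise exceeded the spread between the control arrays. These recoveries therefore do not say how many changed genes either fit would find in the real data.

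A total of 30 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. In simulated data 30 probes were shifted by 0.5 on the log2 scale, and those that represented a tested gene formed a list. That list had a camera adjusted p of 4.0e-16 with the preset correlation and 0.325 with an estimated one. Of 29 random lists 0 passed in either. The estimated version therefore missed the simulated shift in this single draw. The simulated genes varied independently, so the draw cannot show whether the preset correlation is too low for co-regulated lists. Among the lists called below, the estimated correlation ran from -0.057 for nucleotide synthesis to 0.352 for NRF2 targets. It was -0.029 for p53 targets, -0.0047 for DNA replication and -0.0079 for interferon-stimulated genes. In these lists and in nucleotide synthesis it was below the preset 0.01. A correlation above the preset therefore does not account for their higher adjusted p in the estimated version. It was above 0.01 for mitosis (0.038), ribosome biogenesis (0.039) and the proteasome (0.021).

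Named genes followed a rule fixed in advance. It takes LAS1L, the 12 largest rises and falls past the primary threshold with both Las1L arrays outside the control range or, where none passed, the 6 smallest p-values in each direction, up to 4 members of each list by smallest p-value, and a set of genes named whatever their values. Genes with the 12 largest rises and falls in the trend fit, and other list members, were named after their values had been seen. Where both arrays of a group lay under the background limit, the fold is a lower bound, written as at least that fold and computed against the limit. NPM1 was not analysed here.

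Alternatives covered the floor, scaling between arrays, the filter on dim probes, the rule for several probes, the variance model, the threshold, the groups in the fit, array weights and leaving out each array. The planned search for siRNA seed matches in transcripts was not run.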

Results

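LAS1L, a nucleolar protein needed for processing of ribosomal RNA precursors of the large subunit, was depleted in HCT116 cells with 2 different siRNAs, and messenger RNA levels were compared with those of cells given a control siRNA. The series asks about nucleolar stress in cancer cells. There were 2 control arrays and 2 Las1L arrays, 1 for each siRNA. Between 17280 and 17284 probes per array exceeded the background limit. These near-equal counts follow from sorted values that are nearly the same across arrays, and say nothing about array quality. Over the 10466 tested genes, log2 signals correlated at 0.988 between the control arrays and at 0.989 between the Las1L arrays, and between 0.974 and 0.975 across the groups.

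The targeted gene was lower on both Las1L arrays. The single LAS1L probe (ILMN_1774890) gave signals of 770 and 717.5 units with control siRNA, 211.5 with siRNA #1 and 158.1 with siRNA #2. These left 28.4% of the control signal with siRNA #1 and 21.3% with siRNA #2. The log2 fold change was -2.02 with a standard error of 0.19. Its adjusted p in the primary limma fit was 0.0555, just short of the threshold, and it was 2.3e-07 in limma with an intensity trend, which had not been planned for this single value.

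The comparison of Las1L siRNA with control siRNA asked which transcripts differ when LAS1L is depleted. TP53I3, an oxidoreductase, was 4.37-fold higher and MYL2, a myosin light chain, 4.64-fold higher, while COX6A1, a cytochrome c oxidase subunit, was 4.2-fold lower and WARS1, the tryptophanyl-tRNA synthetase, was 3.92-fold lower. In the primary fit 0 of 10466 genes passed an adjusted p of 0.05. The lowest adjusted p in limma was 0.0523, and 2676 genes had an unadjusted p under 0.05. With the planned intensity trend limma passed 1969 genes, 1009 higher and 960 lower, of which 195 and 120 changed at least 2-fold. That count was 0 without Las1L siRNA #1, 0 without Las1L siRNA #2, 813 without control replicate 1 and 1072 without control replicate 2, and it fell to 31 with a floor of 50 and to 0 with no filter on dim probes. The primary fit restricted to probes above background on all 4 arrays passed 857 of 9140 genes, 444 higher and 413 lower, and 786 of these genes also passed with the trend. Both Las1L arrays lay above both controls for 3134 genes and below both for 3114, together 59.7% of genes. A random order of the 4 arrays gives 33.3% for a single gene. The genes share the same 4 arrays and are not independent, so this share is a description and not a test. In what follows, "rose" and "fell" refer to genes past the threshold of the intensity-trend fit, and none of them passed the primary fit. Counts within lists are to be read beside the 1009 that rose and 960 that fell among all 10466 genes.

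By smallest p-value in the primary fit, the leading genes with higher signal were ARHGDIB, at least 3.93-fold higher, CLIC3, a chloride channel protein, at least 3.13-fold higher, MYL2, VHRT, at least 4.4-fold higher, CHST6, a sulfotransferase, at least 2.43-fold higher, and TP53I3. Those with lower signal were MXI1, a MAX-interacting repressor, at least 2.4-fold lower, GCNT3, a mucin glycosyltransferase, at least 2.33-fold lower, WARS1, SPRY4, an inhibitor of receptor tyrosine kinase signalling, 3.62-fold lower, ERLIN1, 2.96-fold lower, and COX6A1. Each of the 12 had an adjusted p of 0.0523 or 0.0555 in the primary limma fit, and each passed with the trend. Among the 12 largest rises, named after their values were seen, were KRT80, an epithelial keratin, 14.1-fold, IQCN, 6.86-fold, and ALDH3B1, 5.7-fold, each with 1 of its 2 control arrays under the background limit, so that the fold rests in part on background. In the same set were CPT1C, at least 4.45-fold, PROM2, at least 3.82-fold, CCNG2, at least 3.71-fold, and MEF2C, at least 2.86-fold. Among the 12 largest falls, NETO2 was 5.37-fold lower and CPSF6 at least 2.54-fold lower.

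**Figure D1:**
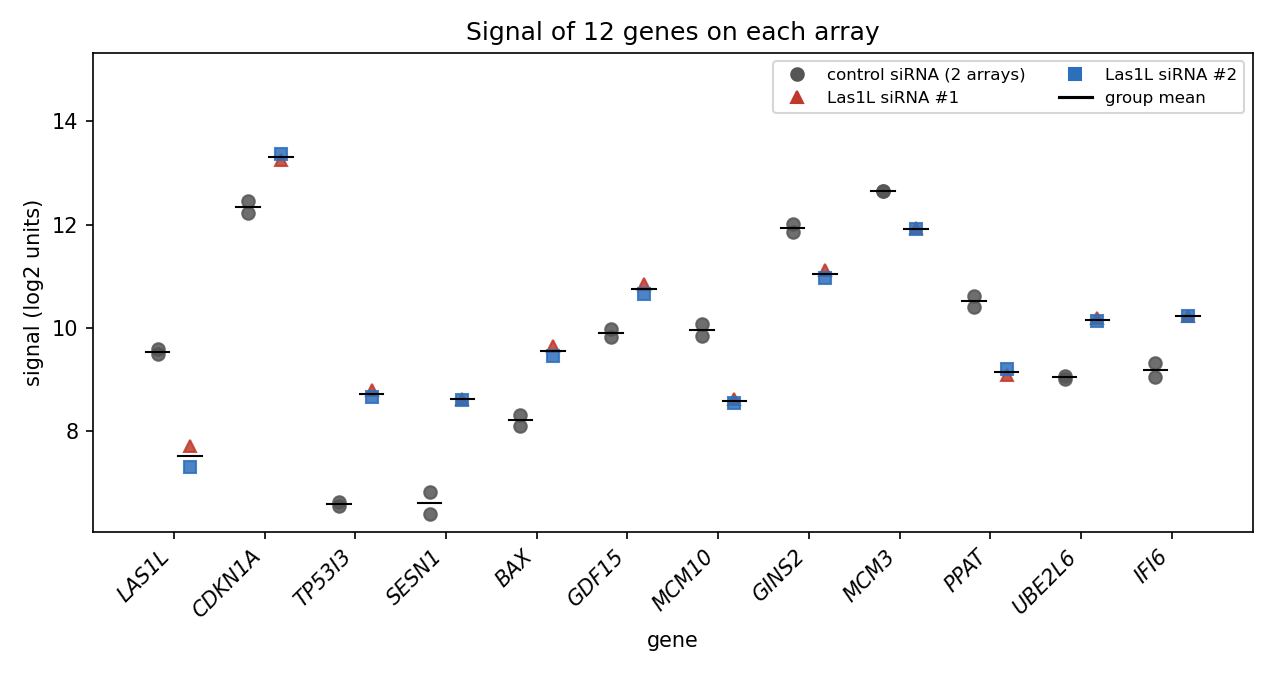
Log2 signal (vertical axis) of 12 genes (horizontal axis) on the control siRNA arrays (circles), the Las1L siRNA #1 array (triangles) and the Las1L siRNA #2 array (squares), with bars at group means. LAS1L lies lower and CDKN1A higher on both Las1L arrays than on both controls, with log2 fold changes of -2.02 and 0.96.

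Targets of the transcription factor p53 were higher as a group. Of 33 measured members 18 rose and 1 fell, and the median log2 fold change was 0.57. TP53I3 rose by 2.13 (SE 0.15 in the trend fit), SESN1, a stress-induced regulator of growth signalling, by 2.01 (SE 0.17), PHLDA3 by 1.66 (SE 0.22) and BAX, a pro-apoptotic BCL2 family member, by 1.35 (SE 0.12). CDKN1A, the p21 cell-cycle inhibitor, rose by 0.96 (SE 0.10) and GDF15, a stress-induced cytokine, by 0.85 (SE 0.10). MDM2, a ubiquitin ligase, had a log2 fold change of 0.73 and did not pass (adjusted p = 0.0744 in limma with the trend). The 1 member that fell was ZMAT3, whose probes disagreed in direction. Adjusted over the list alone, the primary fit passed 18 members as higher and 1 as lower. The list's adjusted p in camera was 2.5e-07, and adjusted p = 0.368 with an estimated correlation. That estimate was -0.029, below the preset 0.01.

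Genes of DNA replication were lower. Of 33 members 18 fell and 0 rose by their representative probes, with a median of -0.44. The probes of the member RFC3 disagreed in direction. MCM10, a replication initiation factor, fell by 1.37 (SE 0.12), GINS2, part of the replicative helicase, by 0.88 (SE 0.10), MCM3, a helicase subunit, by 0.73 (SE 0.08) and CHAF1A, a histone chaperone subunit, by 0.98 (SE 0.17). MCM2 had a log2 fold change of -0.25 and did not pass. Adjusted over the list alone, the primary fit passed 16 members as lower. The list had a camera adjusted p of 7.5e-07, and adjusted p = 0.368 with an estimated correlation. That estimate was -0.0047, below the preset 0.01. Genes of mitosis had a median of -0.20, and 9 of 36 fell, among them CDC25B, a phosphatase that activates mitotic kinases, by 0.69 and KIF11, a spindle motor, by 0.84. CCNB1 had a log2 fold change of -0.22 and MKI67 one of -0.60, and neither passed. Adjusted over the list alone, 0 mitotic genes passed the primary fit, and the camera adjusted p was 0.0013, with adjusted p = 0.531 with an estimated correlation.

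Interferon-stimulated genes were higher. Of 21 measured members 10 rose and 0 fell, with a median of 0.62. The size of that median depended on the setting. It was 0.36 above background on all 4 arrays, 0.31 with a floor of 50, 0.32 with an offset of 64 and 0.24 with no filter. UBE2L6, an enzyme of ISG15 conjugation, rose by 1.12 (SE 0.10), IFI6 by 1.04 (SE 0.11), ISG15, a ubiquitin-like modifier, by 0.77 (SE 0.10) and IRF1, an interferon-regulated transcription factor, by 0.87 (SE 0.13), and IFIT2 was at least 2.53-fold higher. Adjusted over the list alone, 9 passed the primary fit as higher. The camera adjusted p was 1.1e-04, and adjusted p = 0.405 with an estimated correlation. That estimate was -0.0079, below the preset 0.01. Of 5 measured fibroblast, endothelial and leukocyte markers 0 passed either fit. CD14 had a log2 fold change of -0.87 and LYZ one of 0.72, each under the background limit on 1 of the 4 arrays, and the list's median of 0.18 had the opposite sign to its camera direction (adjusted p = 0.959).

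Ribosome production was examined because LAS1L acts in it. Of 49 ribosome biogenesis factors 8 fell and 0 rose, with a median of -0.12, while 960 of all 10466 tested genes fell. WDR12, a large-subunit assembly factor, fell by 0.89 (SE 0.10), NOLC1 by 0.53, NOC2L by 0.66 and NOP56 by 0.43. Adjusted over the list alone 0 passed the primary fit. The camera adjusted p was 0.0188, and adjusted p = 0.68 with an estimated correlation. It was 0.0873 without control replicate 1 and 0.051 without Las1L siRNA #2. The 4 measured LAS1L complex partners, PELP1, TEX10, WDR18 and MDN1, had log2 fold changes of -0.21, -0.17, -0.16 and -0.05, and 0 passed. Large-subunit ribosomal protein genes had a median of 0.02, with 3 of 42 higher (RPL28, RPL21 and RPL13A), and small-subunit genes had a median of 0.01 and a mean of -0.01, with 1 of 26 lower (RPS23). Near-identical pseudogene copies may share these probes. RPL5 and RPL11 had log2 fold changes of -0.08 and -0.05. In the RNA polymerase I machinery TAF1A fell by 0.63 and POLR1D rose by 0.38 among 17 members (camera adjusted p = 0.156).

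Proteasome subunits, enzymes of nucleotide synthesis and NRF2 targets were lower as lists, with fewer than 50% of the members of each past the threshold. Of 26 proteasome subunits 10 fell, led by PSMB5, a catalytic subunit, which fell by 1.16 (SE 0.09), and PSMD1, which fell by 0.61. Their median was -0.23, 1 passed adjusted over the list alone, and the camera adjusted p was 0.0013, with adjusted p = 0.531 with an estimated correlation. Of 17 genes of purine and pyrimidine synthesis 5 fell, including PPAT, the first committed enzyme of purine synthesis, by 1.37 (SE 0.11) and IMPDH1 by 0.79. Adjusted over the list alone 5 passed as lower, and the camera adjusted p was 0.0188, with adjusted p = 0.531 with an estimated correlation. Of 14 targets of the oxidative stress factor NRF2 6 fell, among them GCLM, a subunit of the glutathione synthesis enzyme, by 1.35 and NQO1 by 0.59. Their camera adjusted p was 0.0452, with adjusted p = 0.805 with an estimated correlation, and 1 passed adjusted over the list alone. It was 0.179 without control replicate 2, 0.133 without Las1L siRNA #1 and 0.0667 without Las1L siRNA #2.

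Targets of the amino acid response factor ATF4 moved both ways, with 3 higher and 7 lower of 24 and a camera adjusted p of 0.736. ATF3 rose by 0.89 while TRIB3 fell by 0.50, and DDIT3 had a log2 fold change of 0.42 and did not pass. Of 18 cytosolic tRNA synthetases 4 fell, led by WARS1, which fell by 1.97, and VARS1, which fell by 0.59 (camera adjusted p = 0.112 in the primary fit and 0.0291 with the trend, and adjusted p = 0.752 in the primary fit with an estimated correlation). Of 18 BCL2 family members and caspases 4 rose and 3 fell, with BAX higher and BCL2L2, which fell by 0.78, lower (camera adjusted p = 0.736). MYC had a log2 fold change of -0.16 and did not pass. Of 14 housekeeping genes 1 rose, B2M by 0.51, and 3 fell, HPRT1 by 0.38, YWHAZ by 0.37 and TUBB by 0.33.

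The fry test, which asks whether a list's genes move on balance one way and compares them with no other genes, passed 13 of the 30 lists. Of the 8 lists past the camera threshold, ribosome biogenesis factors (fry adjusted p = 0.124) and NRF2 targets (fry adjusted p = 0.0687) did not pass fry. Lists that passed fry and not camera in the primary fit were glycolysis (0.015), the hypoxia response (0.0297), the heat shock response (0.0422), WNT targets (0.0422), oxidative phosphorylation (0.0428), tRNA synthetases (0.0482) and housekeeping genes (0.0482).

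**Figure D2:**
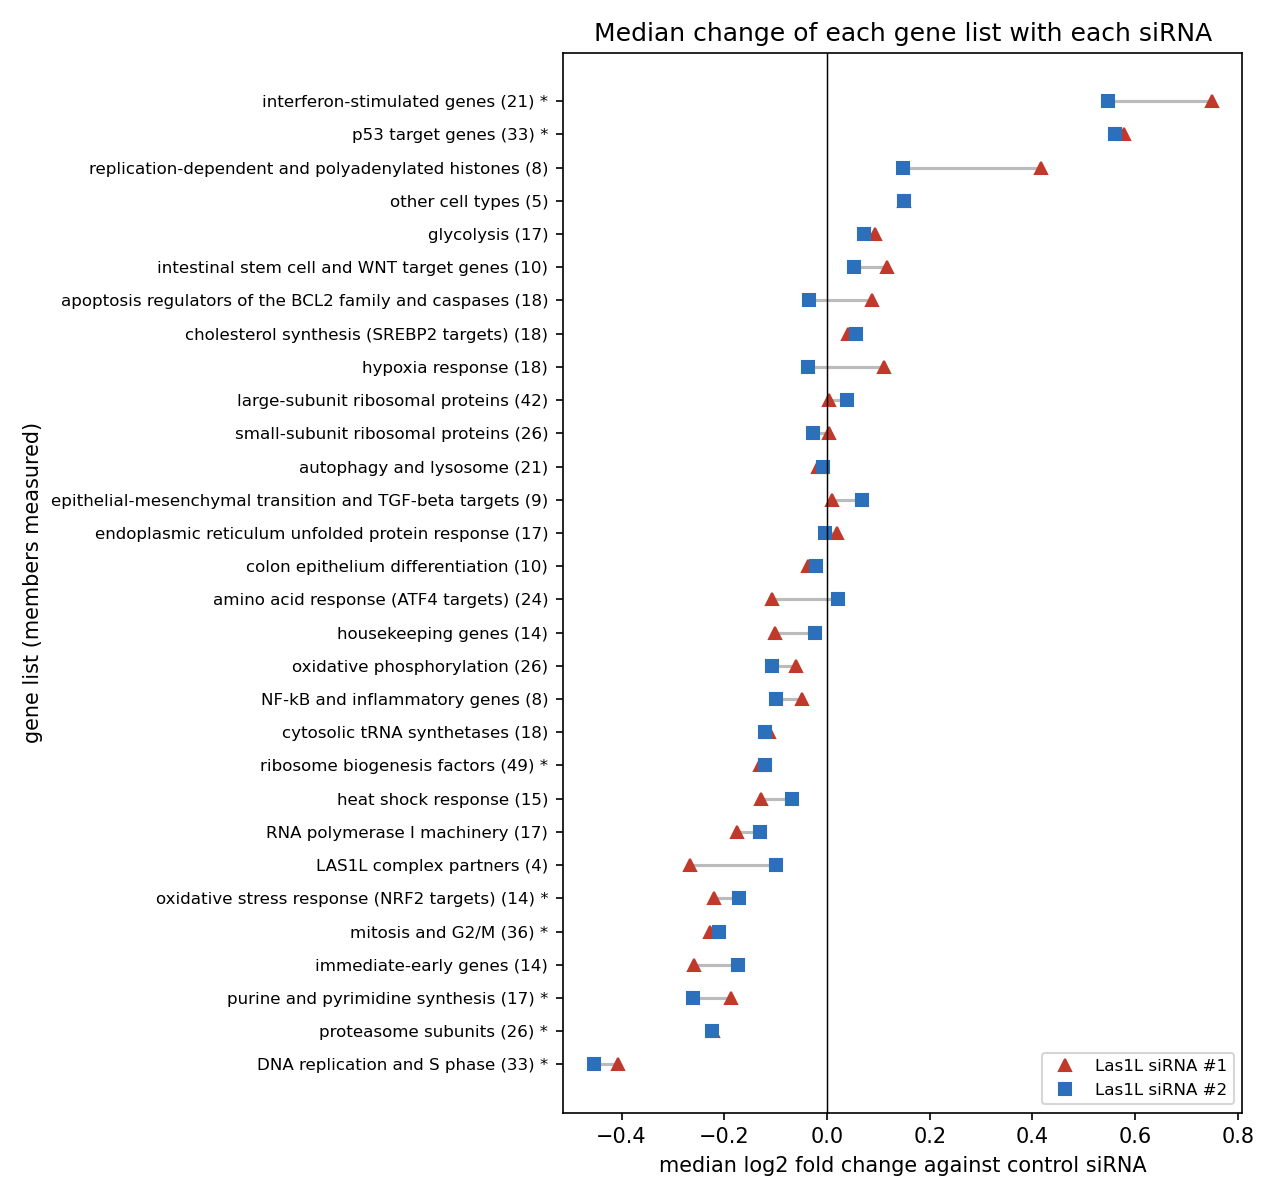
Median log2 fold change against control siRNA (horizontal axis) of each of 30 gene lists (vertical axis, with the number of measured members), for Las1L siRNA #1 (triangles) and #2 (squares). Asterisks mark the 8 lists with a camera adjusted p under 0.05 at the preset correlation, and p53 targets lie at 0.58 and 0.56.

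The 2 siRNAs were then compared with the controls separately and with each other, which asks whether both give the same changes. LAS1L had a log2 fold change of -1.81 with siRNA #1 and -2.23 with siRNA #2, CDKN1A 0.90 and 1.03, and MCM10 -1.33 and -1.41. The median of p53 targets was 0.58 with siRNA #1 and 0.56 with siRNA #2, that of DNA replication genes -0.41 and -0.45, and that of interferon-stimulated genes 0.75 and 0.55. Across the 10466 genes, which are not independent replicates, the fold changes of the 2 siRNAs correlated with a Pearson r of 0.761 and a Spearman coefficient of 0.721, and 78.5% of genes had the same sign.

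These comparisons share their control arrays. Simulated unchanged groups against shared controls, simulated too, gave a mean r of 0.335 and the same sign in 60.6% of genes over 100 draws. All simulated arrays varied alike, so this r follows from sharing the controls and not from the real control arrays. The observed covariance was 0.175 and the simulated one 0.0533. The spread between the 2 control arrays gave 0.0315, so the simulated noise exceeded that spread. With a different control array for each siRNA, so that no array was shared, r was 0.561, or 0.537 with the controls exchanged. In the 3-group limma fit 0 genes passed for siRNA #1, where 1557 had an unadjusted p under 0.05, and 0 for siRNA #2, where 1665 did. On probes above background on all 4 arrays limma passed 109 genes for siRNA #1 and 180 for siRNA #2. Of these, 43 were higher with both and 43 lower with both, where independent lists would share 0.539 and 0.53. Simulated unchanged groups against shared controls gave 0 calls for either siRNA in 100 draws, which says nothing about how real calls would overlap, so part of the excess may come from the shared controls. Directly between the siRNAs, limma passed 0 genes without the trend, where 361 had an unadjusted p under 0.05, and 0 with the trend, where 216 did, and 0 of 30 lists passed in camera (adjusted p = 0.997 for each). With 1 array per siRNA this does not show that the siRNAs act alike.

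**Figure D3:**
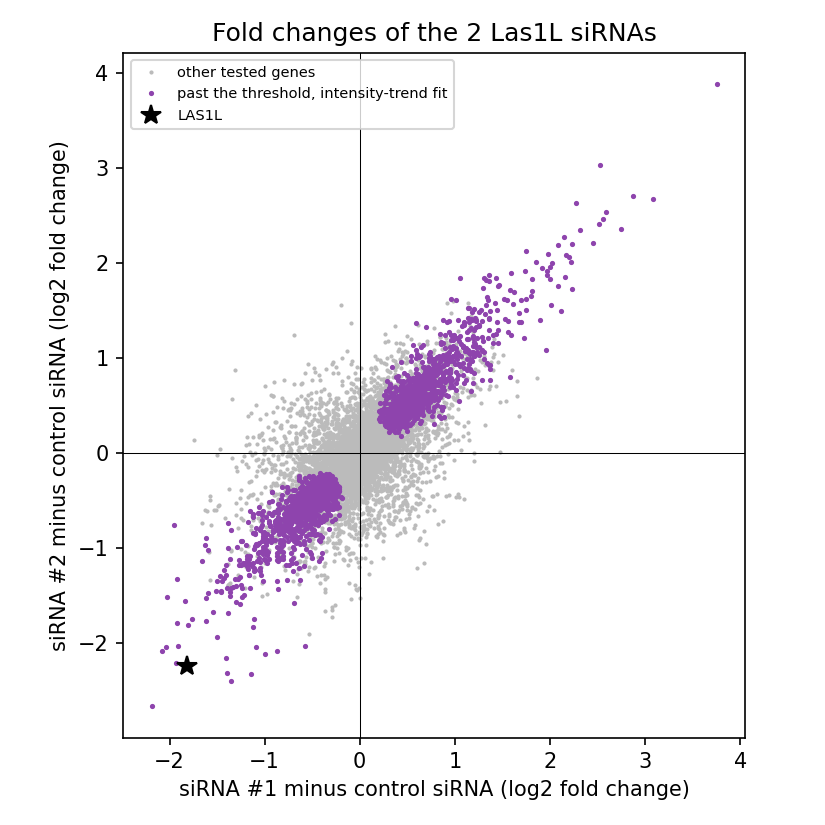
Log2 fold change against control siRNA of each tested gene with Las1L siRNA #1 (horizontal axis) and #2 (vertical axis), with the 1969 genes past the threshold of the intensity-trend fit in purple and LAS1L as a star. The points lie along the diagonal (r = 0.761), and both axes share the same control arrays.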

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

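The setting with an offset of 64, and the alternatives of the intensity-trend count other than the fit with no trend, were chosen after seeing the data, as were the trend, robust and 0.1 settings for LAS1L alone. The count of changed genes was computed in 34 settings, 17 without and 17 with the trend. It was 0 in 13 of them and reached 2658, so no single count stands for this comparison. Without the trend it was 0, and it became 160 with a floor of 50, 12 with no filter, 857 above background on all 4 arrays, 566 with a stricter background limit, 469 with the mean over probes, 1969 with the intensity trend, 926 at an adjusted p under 0.1 and 1503 with the offset of 64. With the trend it was 1969, and it became 31 with a floor of 50, 0 with no filter, 222 with 3 groups and 0 with no intensity trend, and it ranged from 0 to 1072 when 1 array was left out, which leaves fewer samples. Of the 31 genes at a floor of 50, 23 were among the 1969. The cause was not tested. For siRNA #1 the count of 0 became 800 with no filter, 109 above background on all 4 arrays and 859 with the offset, and for siRNA #2 it became 746, 180 and 970. Between the siRNAs it became 1134 with no filter. In 79.4%, 76.4% and 89% of the genes called with no filter in these 3 comparisons, both control values sat at the floor, with no spread between them.

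The correlation of the siRNAs became 0.848 with a floor of 50, 0.675 with no filter, 0.819 above background on all 4 arrays, 0.816 with the stricter limit, 0.846 with the offset, 0.908 in the brighter 50% of genes, 0.561 and 0.537 with disjoint controls, and 0.789 to 0.791 without 1 control. The LAS1L fold change of -2.02 passed the threshold above background on all 4 arrays, with the stricter limit, with the mean over probes, with the trend and at 0.1, and with the offset, where it was -1.71. It ranged from -2.23 to -1.81 without 1 array and kept its direction throughout. The number of lists past the threshold was 8, between 6 and 9 in all other settings, and 0 with an estimated correlation. That setting gave adjusted p-values of 0.368 for p53 targets and for DNA replication, 0.405 for interferon-stimulated genes, 0.531 for mitosis, proteasome and nucleotide synthesis, 0.68 for ribosome biogenesis and 0.805 for NRF2 targets. NRF2 targets also had 0.0822 with 3 groups, 0.0501 above background on all 4 arrays and 0.0521 with the stricter limit, and 0.0198 to 0.179 without 1 array, and ribosome biogenesis 0.0124 to 0.0873. For p53 targets, DNA replication, interferon-stimulated genes and nucleotide synthesis the estimated correlation was below the preset 0.01. A correlation above the preset therefore does not account for the higher adjusted p-values of these lists. The cause of these shifts was not tested further. None of the other named genes reversed direction with a value beyond its standard error.

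Not run were background correction from the table of detection p-values, the siRNA seed matches, robust camera, leaving out a control in the single-siRNA fits, which leaves no residual degrees of freedom, and the correlation among genes passed by the primary fit, of which there were 0. The deposited table, planned as an alternative, is the source of all values. No paired analysis was possible because the control numbers name replicates and the Las1L numbers name siRNAs. Signal over background limits dim genes, whose changes are bounded by the floor.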

Other observations

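The tests in this part on single siRNAs, dim probes, the spread of dim probes and the splits of the arrays were chosen only after the results were seen. Several lists moved in both directions, in the intensity-trend fit of limma. In autophagy and lysosome, MAP1LC3B, an autophagosome membrane protein, rose by 1.19, WIPI1 by 1.30, ULK1, the kinase that starts autophagy, by 0.61 and LAMP2 by 0.54, while GLA fell by 0.46, among 21 members (camera adjusted p = 0.795, with median -0.00476 and mean 0.0968). In the hypoxia response ANGPTL4 rose by 2.04, with 1 of its 2 control arrays under the background limit, and NDRG1 fell by 1.00, as did SLC2A1, a glucose transporter, by 0.64, with 3 higher and 5 lower of 18 (camera adjusted p = 0.736, with median 0.04 and mean -0.08). Among immediate-early genes EGR1 fell by 1.28, FOSL1 by 0.68 and DUSP6 by 0.51, and ATF3 rose, with 2 higher and 4 lower of 14 (camera adjusted p = 0.182). In oxidative phosphorylation, by contrast, only 1 member of 26 passed, SDHD, a succinate dehydrogenase subunit, which fell by 1.69 (camera adjusted p = 0.195).

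In glycolysis ALDOC rose by 0.80 and HK2 by 0.48 among 17 genes (camera adjusted p = 0.473). Among WNT targets CCND1, a G1 cyclin, rose by 0.75 and DKK1 by 0.42 (10 genes, adjusted p = 0.615), and among inflammatory genes LCN2 rose by 1.74, with 1 of its 2 control arrays under the background limit, while IER3 fell by 0.49 and SOD2 by 0.46 (8 genes, adjusted p = 0.736). CCN1 rose by 0.92, TPM1 by 0.56 and ITGA5 fell by 0.60 in the epithelial-mesenchymal list (9 genes, adjusted p = 0.736). KLF4 fell by 0.65 and CDH1 rose by 0.43 among colon differentiation genes (10 genes, adjusted p = 0.795). TM7SF2 rose by 1.00 and MSMO1 fell by 0.61 in cholesterol synthesis (18 genes, adjusted p = 0.945). HSPB1 rose by 0.57 and HSPD1 fell by 0.27 in the heat shock list (15 genes, adjusted p = 0.473). CANX rose by 0.43 and DNAJB9 by 0.49 in the unfolded protein response (17 genes, adjusted p = 0.959), and the histones H2BC12 and H2BC5 rose by 0.41 each (8 genes, adjusted p = 0.536).

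The rise of p53 targets was set against 3 explanations. An off-target effect of a single siRNA would leave the other siRNA's array near the controls. The lowest of the 4 list medians, each Las1L array against each control array, was 0.506. The central range of random lists matched on expression, with the extremes left out, was -0.15 to 0.14. The rise was thus present with each siRNA, as had been seen before this test was chosen. Random lists of unrelated genes may vary less than co-regulated targets. Off-target effects of both siRNAs would give the same medians and cannot be told apart from LAS1L depletion. Noise of dim probes would vanish among bright ones, but the 30 members above background on all 4 arrays had a median of 0.54 with a floor of 50. An effect of the control siRNA itself cannot be told apart from LAS1L depletion, because there were 0 arrays of untransfected cells or of other siRNAs. LAS1L depletion may underlie the pattern and remains an untested hypothesis.

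The rise of interferon-stimulated genes was weighed in the same way. The lowest of the 4 medians was 0.424, and the central range of random lists ended at 0.26. The rise was thus present with each siRNA, which is at odds with an off-target effect of a single siRNA. That too had been seen before the test was chosen. Off-target effects of both siRNAs would give the same medians and cannot be told apart from LAS1L loss. Dim probes as the whole cause are at odds with the median of 0.362 over 18 bright members. The central range of random lists ended at 0.18 there, and that filter also drops members rising from below background. A response to double-stranded RNA that both Las1L siRNAs raise more than the control siRNA cannot be told apart from an effect of LAS1L loss, with 0 arrays of untransfected cells or of other siRNAs. Both could contribute, and neither was tested.

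The contrast between 0 genes without an intensity trend and 1969 with it was examined too. The median residual SD was 0.425 for the 1332 genes under the background limit on at least 1 array and 0.118 for the other 9134, a ratio of 3.6. This is consistent with dim probes inflating the variance that all genes share in the fit without a trend, as are the counts without the trend of 857 above background on all 4 arrays, 566 with the stricter limit, 1503 with the offset of 64 and 160 with a floor of 50. The mean over probes gave 469 genes with as many tested as in the primary fit, and the trend count fell to 31 with a floor of 50. With no filter, which adds dim probes and tested 20039 genes, the count without the trend was 12. That rise from 0 is not accounted for by this explanation. The cause of each was not tested. Of the 3 splits of the 4 arrays into pairs only 1, the real one, gave 1969 genes and the highest other gave 0, and 3 splits are too few for a share under 0.05.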
